A study of Mus musculus with 4 samples.

How the data were processed

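Single-cell RNA sequencing was done on murine lung adenocarcinomas of 2 genotypes. Per the labels' protocols, tumours were started with an adenovirus that expresses Flp recombinase from the surfactant protein C promoter. Flp switched on a tamoxifen-dependent Cre (CreERT2) and deleted p53. Mice received tamoxifen at 120 mg/kg on 4 days, 10 weeks after initiation, and tumours were taken at week 12. KP mice carried 1 floxed copy of Foxa1 and of Foxa2, while KPF1F2 mice were labelled as floxed for both genes. Dissociated tumour cells were loaded either before or after magnetic depletion of cells positive for CD45 (leukocytes) or CD31 (endothelium). This gives 4 groups with 1 library each.

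The deposited matrices hold counts: each value is the number of unique molecular identifiers (UMIs) of a gene in a droplet barcode, made with Cell Ranger 6.0.0 per the file headers. The genome build was mm10, per the submitters' processing notes, and libraries were 10x Genomics 3′ gene expression version 3.1, per the labels' protocols. The settings of that run, its annotation and its treatment of strand are not given in the sources used here. The matrices list 28006 features, of which 27645 have an identifier in the GENCODE mouse release 21 annotation of GRCm38, from which positions were taken. Added features comprise CRE-ERT2, EGFP, UPRT_short and 5 entries that carry the Foxa1 or Foxa2 identifier with a suffix (Foxa1_1, Foxa1_2, Foxa2_1, Foxa2_2, Foxa2_3). The files do not say which part of each gene these pieces cover. Cebpd, a member of a fixed list, was not analysed here.

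The matrices held 5963 barcodes and 63010016 UMIs for KP pre-depletion, 4662 and 47805086 for KPF1F2 pre-depletion, 8536 and 58986043 for KP post-depletion, and 4415 and 62051171 for KPF1F2 post-depletion. Cells were kept with at least 1000 UMIs, at least 500 genes and at most 20% mitochondrial UMIs. The doublet caller scrublet, in scanpy 1.11.5, marked under 0.5% of cells in every library at its automatic threshold. The rule fixed for that case removed the highest-scoring 0.8% of cells per 1000 barcodes, which were 181, 131, 247 and 91 cells in that order. The cells kept numbered 3616, 3377, 3375 and 2475, with medians of 8312, 7080, 9595 and 16410 UMIs.

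Counts of all libraries were log-normalised to 10000 per cell, 2000 variable genes and 30 principal components were taken, and cells were joined by 15 exact nearest neighbours and clustered by the Leiden method (igraph 0.11.9) at resolution 1 with no batch correction. A cluster was called after a cell type when at least 3 markers of a set fixed beforehand were raised 2-fold over the median cluster and no other set had more markers among its 10 leading genes. There were 20 marker sets. The epithelial set that named clusters used general epithelial genes only. Alveolar and squamous genes counted as epithelial where leading genes were compared, so they could keep a cluster in that class. Clusters 4, 8 and 31 had epithelial genes but a low median depth for their libraries and no marker among their leading genes, and stayed unnamed.

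UMIs were summed per library over epithelial-like cells and given as CPM, the UMIs of a gene scaled to the total of that sum. Folds are log2 of KPF1F2 over KP with 1 CPM added to each side, taken within a depletion state. Genes with a mean of 20 CPM or more entered the comparison. With 1 library per group there was no replicate from which to measure error, so no test was made and no p-value is given. Intervals are 95%, exact Poisson for CPM, exact conditional binomial for ratios of counts (without the added CPM) and Clopper-Pearson for shares, and cover counting error only. A count of 0 was given the limit of 3 counts. Same-genotype folds, post-depletion against pre-depletion, served as a yardstick. List medians were placed among 10000 random lists of the same size matched on expression, as a description of these libraries.

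Genes were named by a rule fixed before the data were examined. It took 18 genes in any case, and the first 12 higher and 12 lower genes with a log2 fold of 1 or more of the same sign in both states, the smaller of which exceeded both same-genotype differences. Left out of that ranking were gene models, ribosomal, mitochondrial, immunoglobulin, T cell receptor, haemoglobin and sex-linked marker genes, and genes higher in the non-epithelial cells of the library with the higher value. Non-epithelial cells were all cells kept outside the epithelial-like class, including the shallow clusters 4, 8 and 31. Post-depletion those clusters held 717 of 861 such cells in KP and 280 of 811 in KPF1F2. For each of 26 fixed lists, up to 4 members in the main direction and 2 in the other were named. Some genes this rule names are not reported here. In non-epithelial classes with 100 cells or more in both libraries of a state, 5 genes each way with a mean of 50 CPM were named, leaving out genes higher in other cells of the library with the higher value. The added features, Xist, Ddx3y, Ptprc, Gzme, Psca, Sftpd, Csf2 and the genes described as library-wide were chosen after their values were seen, as were all values for cells with a CRE-ERT2 UMI.

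To compare shares of cells with a UMI, each cell was thinned to 3000 UMIs and shallower cells were left out. Among epithelial-like cells this left out 29, 7, 179 and 125 cells, in the library order above. Alternatives were edgeR 4.0.16 TMM factors, DESeq2 1.42.0 size factors, no CPM minimum or one of 100, pseudocounts of 0.1 and 5 CPM, stricter and looser cell filters, doublets kept, resolutions 0.5 and 2, epithelial cells chosen by a marker rule per cell, equal weight per cell, subtraction of 5% free RNA, cells without Mki67 and Top2a UMIs, and thinning to 1500 UMIs or none. Free RNA was not measured: its profile was that of the non-epithelial cells of the same library. Added after the data were seen were 4 alternatives: cells with a CRE-ERT2 UMI, epithelial-like cells without clusters under 20 CPM of CRE-ERT2 over all libraries, inclusion of the shallow clusters, and genes outside chromosomes X and Y.

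The steps were tested on simulated data for the epithelial comparison, with 200 of 5558 genes given a known fold. Counts were drawn with a negative binomial dispersion of 0.02, a spread beyond counting error, and the same levels in both states. Differences between single mice or in the mix of cells were not simulated. In the libraries themselves, 63 genes in KP and 88 in KPF1F2 differed 2-fold between the states. Genes at least 2-fold different in both states were counted, without the comparison with same-genotype differences. They were 8 of 50 at a simulated 2-fold difference, 43 of 50 at 3-fold, 46 of 50 at 4-fold and 42 of 50 at 8-fold. Of genes with no difference, 0 of 5382 were counted. Those missed at 4-fold and 8-fold had dropped below the CPM minimum. For the neutrophil-like comparison over 2480 genes, 27, 42, 41 and 39 of 50 genes passed at 2-fold, 3-fold, 4-fold and 8-fold, with 23 of 2311 genes that had no difference. The ratio interval held the true value in 96.5% of 4000 simulated pairs. Figures were drawn with matplotlib 3.10.9, and other steps used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and R 4.3.3.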

Results

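The series title and design name the question: what Foxa1 and Foxa2, forkhead transcription factors of endodermal tissues, do for growth and cell identity in Nkx2-1-positive lung adenocarcinoma. UMI counts were compared between KP and KPF1F2 tumours, before and after depletion of leukocytes and endothelium, with 1 library in each of the 4 groups. There are no replicates, so each difference below is between libraries, and intervals cover counting error only. The labels do not say whether both libraries of a genotype came from the same mice. The titles of 3 libraries begin with 18836 and that of KPF1F2 pre-depletion with 18385, so the post-depletion pair, which shares a number, is the main comparison. Epithelial-like cells numbered 573 in KP and 176 in KPF1F2 before depletion, and 2514 and 1664 after it, with medians of 23929, 21205, 12988 and 21462.5 UMIs.

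The deleted genes were read first. Foxa1 (ENSMUSG00000035451, chromosome 12, 57540628 to 57546916, minus strand, 2 exons) and Foxa2 (ENSMUSG00000037025, chromosome 2, 148042877 to 148046969, minus strand, up to 3 exons) had 0 UMIs under their own identifiers in all barcodes of all 4 libraries. UMIs were found only under the added pieces, with very few for Foxa2. The piece Foxa1_2 stood at 16.3 CPM in KP and 11.1 in KPF1F2 pre-depletion, and at 16.7 (15.5 to 17.97) in KP and 3.46 (2.94 to 4.03) in KPF1F2 post-depletion, a ratio of 4.83 (4.07 to 5.77). In the same cells Foxa1_1 was higher in KPF1F2 post-depletion, at 7.95 against 2.72 CPM, and its pre-depletion values of 5.66 and 4.18 CPM did not differ beyond counting error. In cells with a CRE-ERT2 UMI, the log2 fold of Foxa1_2 was −3.63 pre-depletion and −3.75 post-depletion, against −0.51 and −1.99 over all epithelial-like cells. Cells with a CRE-ERT2 UMI numbered 248 in KP and 50 in KPF1F2 pre-depletion, and 840 and 565 post-depletion. Their median depths were 36287, 30994.5, 21102 and 34695 UMIs, so this choice favours deep cells, and pre-depletion values rest on few KPF1F2 cells. Foxa2_1 had 3, 0, 7 and 10 UMIs over all barcodes of KP and KPF1F2 pre-depletion and KP and KPF1F2 post-depletion, and Foxa2_2 and Foxa2_3 had none, so loss of Foxa2 could not be judged. Whether depth or the way reads were counted over the pieces left so few was not tested. Since the files do not say which exons the pieces cover, they check the labels only in part: Foxa1_2 was lower in both libraries labelled KPF1F2.

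**Figure D1:**
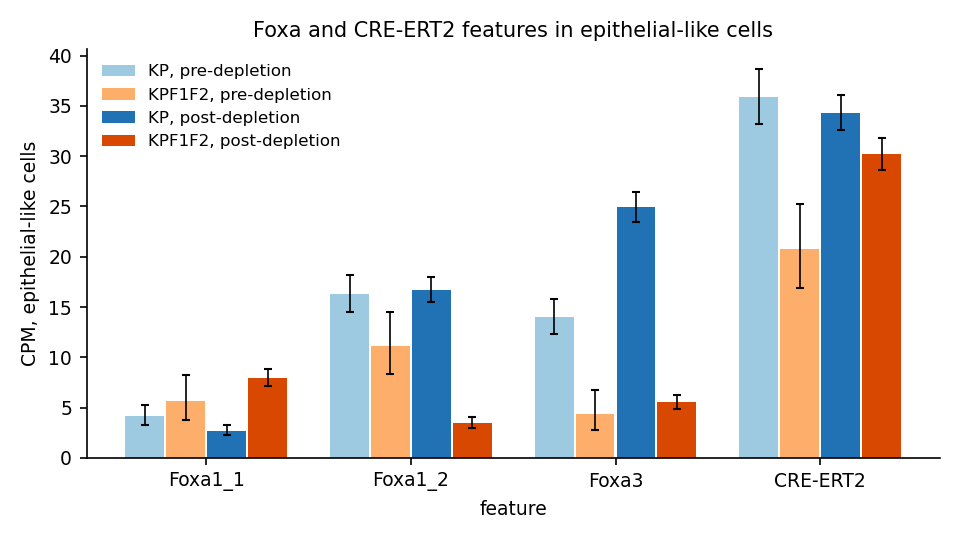
Bars give CPM of Foxa1_1, Foxa1_2, Foxa3 and CRE-ERT2 in the epithelial-like cells of the 4 libraries, with exact Poisson 95% intervals. Foxa1_2 stands at 3.46 CPM in KPF1F2 post-depletion against 16.7 in KP post-depletion, and Foxa3 at 5.51 against 24.9.

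The related factor Foxa3 (chromosome 7, 19013284 to 19023538) was also lower, at 5.51 against 24.9 CPM post-depletion and 4.40 against 14.0 pre-depletion. Nkx2-1, the lineage factor of lung epithelium (chromosome 12, 56531958 to 56536908), was not: it stood at 185 CPM in KP and 206 in KPF1F2 pre-depletion, and at 146 and 175 post-depletion. After thinning, 36.1% (34.1 to 38.0) of KP and 42.3% (39.8 to 44.8) of KPF1F2 epithelial-like cells had an Nkx2-1 UMI post-depletion, and 71.9% and 83.2% unthinned. Alveolar macrophage-like and macrophage-like cells, pooled, which should lack it, gave 0.834% in KP and 0.0966% in KPF1F2 pre-depletion, where epithelial-like cells gave 47.4% and 51.5%. Their median depths were 18235 and 19509 UMIs against 23929 and 21205 in epithelial-like cells. Sex-linked genes differed between the genotypes: Xist (chromosome X) stood at 685 and 721 CPM in the KP libraries and at 0.210 and 0.324 in KPF1F2, while Ddx3y (chromosome Y) stood at 0 in KP and at 28.7 and 33.9 CPM in KPF1F2.

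Between genotypes, KPF1F2 epithelial-like cells had far less of a set of stomach and gut genes and more of alveolar type 1 and antigen presentation genes. Gkn2, a gastrokine of the stomach lining, stood at 884 and 590 CPM in KP and had 0 UMIs in KPF1F2 pre-depletion (at least 1407-fold lower) and 1 UMI post-depletion. Tff1, a gastric trefoil peptide, had 0 UMIs in both KPF1F2 libraries, at least 88.5-fold lower pre-depletion and at least 660-fold lower post-depletion. On the other side, Serpinb2, a serine protease inhibitor, was higher by a log2 fold of 3.43 pre-depletion and 3.90 post-depletion, and Aqp5, a water channel of type 1 cells, by 1.87 and 2.11. Of 5675 genes compared, 184 were at least 2-fold higher and 130 at least 2-fold lower in KPF1F2 in both states, and 6 were 2-fold different in opposite directions. The split was 152 and 153 with TMM factors and 156 and 152 with DESeq2 size factors, so the excess of higher genes depends on the scaling. As a yardstick, 63 genes differed 2-fold between the KP libraries of the 2 states and 88 between the KPF1F2 libraries.

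The clusters that held most of the epithelial class overlapped in part: clusters 1, 2, 9, 20 and 28 in KP and clusters 3, 21 and 1 in KPF1F2. The folds of the 2 states correlated across genes at r = 0.758, with genes not independent replicates. In cells with a CRE-ERT2 UMI, the counts were 233 higher and 171 lower, of which 146 and 106 were among the genes above. TMM factors moved the median fold of all genes pre-depletion from 0.09 to −0.02, and folds here are relative to total UMIs. Genes on chromosomes X and Y made up 5.41% of the 2-fold genes and 2.82% of the genes compared.

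Among the 12 genes that led the higher side, UPRT_short, an added feature, was absent in both KP libraries and stood at 182 and 209 CPM in KPF1F2 (at least 1116-fold and at least 3005-fold higher). The chitinase-like Chil4 was higher by 7.81 and 3.15, Smim6 by 3.68 and 3.08, and the leucine-rich Lrrc26 by 3.49 and 2.78, giving pre-depletion first. Cnfn, a gene of the cornified envelope, was higher by 6.61 and 3.02, the first against a single KP UMI, with a ratio of 1880 (336 to 74415). The cytochrome P450 gene Cyp4b1 was higher by 2.87 and 2.89, Ly6i by 2.61 and 2.86, Itm2a by 2.50 and 2.60 and the laminin receptor subunit Itga7 by 2.27 and 2.52. The collagen VI genes Col6a2 and Col6a1 were higher by 2.93 and 2.81, and by 2.27 and 2.34.

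On the lower side, besides Gkn2 and Tff1, the log2 fold of Apob, the apolipoprotein of lipid particles, was −5.99 (2 UMIs in KPF1F2) and −5.51. Ctse, the aspartic protease cathepsin E of the stomach, stood at −5.32 and −4.83, and Rbp4, the retinol carrier, at −3.34 and −5.32. Of genes for secreted peptides, Pyy had 0 UMIs pre-depletion (at least 45.6-fold lower) and a log2 fold of −5.68 post-depletion. Npy was at least 36.8-fold and at least 2094-fold lower, and Qrfp at least 29.5-fold lower pre-depletion with 1 UMI against 2667 post-depletion. Dcpp1 was at least 24.1-fold and at least 1121-fold lower. The homeobox gene Prrx2 stood at −3.87 and −4.35, Bex2 at −3.49 and −3.62 and the creatine kinase Ckb at −3.09 and −3.24. Gzme was lower as well, by folds of −2.18 and −2.56. Several of these genes led clusters mostly of KP cells. Npy and Qrfp led cluster 28, with 10 KP cells pre-depletion, 99 post-depletion and 0 in KPF1F2. Gkn2 and Gzme were leading genes of cluster 9, with 62 and 285 KP cells and 0 in KPF1F2. Ctse and Pyy were leading genes of cluster 20, with 105 and 671 KP and 2 and 49 KPF1F2 cells. A fold over the whole class does not separate fewer such cells from less RNA per cell.

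**Figure D2:**
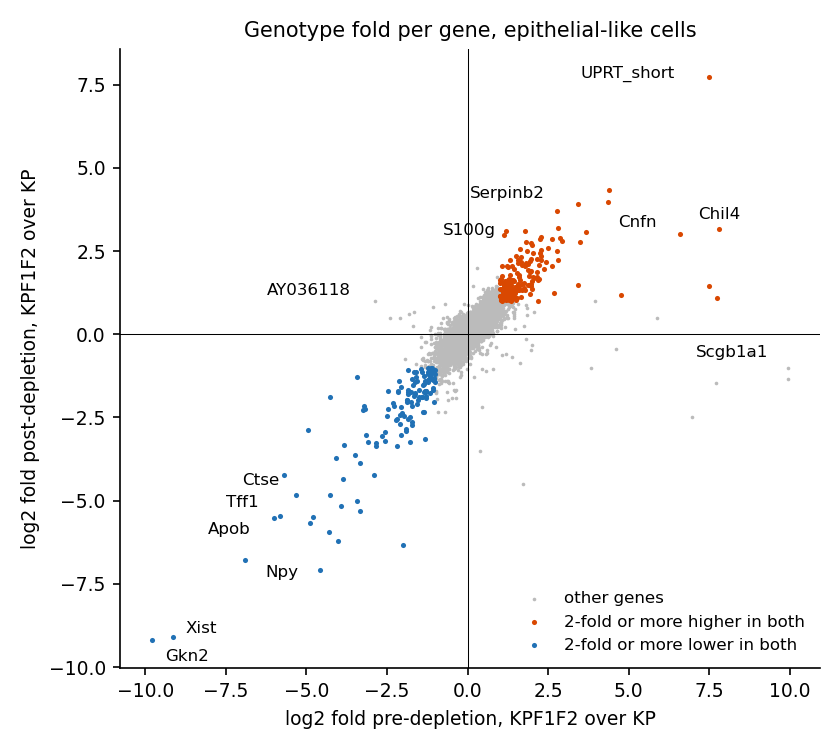
Each point is 1 of the 5675 genes compared, with the log2 fold of KPF1F2 over KP in epithelial-like cells pre-depletion on the x axis and post-depletion on the y axis. Orange points (184) and blue points (130) were at least 2-fold higher or lower in both states; Scgb1a1 and AY036118 lie on opposite sides in the 2 states.

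Gastrointestinal genes had a median log2 fold of −3.01 pre-depletion and −2.85 post-depletion over 6 measured members, lower than all matched random lists (percentile 0 in both). Gkn2, Tff1 and Ctse were at least 2-fold lower in both states, Cldn2, a claudin, stood at −0.71 and −0.55, and Psca at 1.62 and −0.86. Pigr, the receptor that carries antibodies across epithelia, was higher by 1.28 and 0.87. Both medians lie in a wide gap between Ctse and the next member, Cldn2 pre-depletion and Psca post-depletion, and move with the setting. Post-depletion the median ranged from −4.83 with genes outside chromosomes X and Y to −0.44 with equal weight per cell. Hnf4a, a regulator of gut and liver identity (chromosome 2, 163506808 to 163572910), stood at 19.5 CPM in KP and 0 in KPF1F2 pre-depletion (at least 31.1-fold lower) and at 24.6 and 0.346 CPM post-depletion. After thinning, 6.47% (5.50 to 7.54) of KP and 0.130% (0.0157 to 0.469) of KPF1F2 epithelial-like cells had an Hnf4a UMI post-depletion, and 22.7% and 0.481% unthinned. Pre-depletion it was 3.68% in KP and 0 of 169 cells in KPF1F2, which allows up to 1.78%, with 0 of 1079 KP cells of the pooled macrophage classes.

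Type 1 alveolar genes were higher, with medians of 0.72 and 1.01 (percentile 100 in both). Of 20 measured members 16 were higher in both states and 6 at least 2-fold, including Ager (1.25 and 1.44) and the caveolin Cav1 (1.93 and 1.86). Igfbp2 stood at 1.88 and 1.48 and Hopx at 1.56 and 0.92, while the growth factor Vegfa (−0.41 and −0.85) and Cldn18 (−0.25 and −0.27) went the other way. Post-depletion, Igfbp2 rested on low values, 0.581 CPM in KP and 3.41 in KPF1F2. In cells with a CRE-ERT2 UMI it stood at −1.31 and 1.19, and the list medians were 0.89 and 0.71.

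Type 2 alveolar genes split. Their median was 0.16 (percentile 66.4) and 0.43 (percentile 99.6), but −0.75 (percentile 0) and −0.44 (percentile 0.01) in cells with a CRE-ERT2 UMI. The same-genotype median in KP, post-depletion over pre-depletion, was −0.56. That is larger in size than both genotype medians over all epithelial-like cells. S100g (1.97 and 2.74), the chitinase-like Chil1 (1.24 and 1.56), Cd36 (1.18 and 1.44) and the protease Napsa (1.17 and 1.59) were higher. Of the surfactant genes, Sftpc (−1.15 and −1.09), Sftpb (−0.55 and −0.75) and Sftpa1 (−0.60 and −0.28) were lower and Sftpd (0.50 and 0.97) was higher. In cells with a CRE-ERT2 UMI they stood at −4.42 and −3.93, −1.84 and −1.45, −4.67 and −3.34, and 0.15 and 0.66. Clusters 1, 27 and 34, which had little CRE-ERT2 over all libraries together, held 25.0% of KPF1F2 epithelial-like cells post-depletion and 89.0% of their Sftpc UMIs, against 29.95% and 44.3% in KP. The same cluster need not hold like cells in both genotypes: in cluster 1, CRE-ERT2 stood at 13.8 CPM in KP and 0.984 in KPF1F2 post-depletion. Lyz2 stood at 0.56 and 0.86 but was higher in non-epithelial cells.

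Transitional alveolar genes, raised when type 2 cells pass towards type 1, had medians of 0.59 (percentile 99.9) and 0.31 (95.5). The same-genotype median in KP was 0.48, larger than the post-depletion genotype median. Nupr1 (1.90 and 1.76), Sfn (1.58 and 1.51), Itgb6 (1.70 and 1.51) and Cldn4 (1.32 and 0.85) were higher, Tm4sf1 (−2.91 and −4.23) and tissue factor F3 (−1.38 and −1.53) lower, and Krt8 stood at 0.71 and 0.19. Squamous genes had medians of 0.40 and −0.31 over 8 members (percentiles 95.2 and 1.52). Their same-genotype median in KP was 0.50, larger in size than both. Serpinb2, given above, was the only member at least 2-fold higher in both states. Serpinb5 stood at 0.82 and 0.56, Perp at 0.52 and 0.15, Krt14 at −3.43 and −1.29 and Ly6d at −0.38 and −1.72. Krt5 was at most 2.51 CPM and Sox2 at most 3.14 CPM in any library.

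Club cell genes had medians of 4.76 (percentile 100) and −0.60 (0.01), with Cyp2f2 at 4.76 and 1.17, Bpifb1 at least 1317-fold higher pre-depletion and 1.09 post-depletion, and Aldh1a1 at 3.96 and 0.99. The same-genotype median of the list was 1.36 in KP and −3.54 in KPF1F2, both larger in size than the post-depletion genotype median. The sign of that post-depletion genotype median depends on the setting. It was 0.33 with doublets kept, 0.84 at resolution 0.5, 0.16 without Mki67 and Top2a UMIs and 1.45 without clusters low in CRE-ERT2. In cells with a CRE-ERT2 UMI the medians were 1.53 and 0.41 over 5 members. Other settings kept it negative. Cluster 34, led by club cell genes, held 0 KP and 6 KPF1F2 cells pre-depletion and 27 and 7 post-depletion. Embryonic lung genes stood at −0.22 and −0.35 (percentiles 6.99 and 1.90). In that list Cpm (0.86 and 1.17), Sox9 (1.23 and 0.58) and Gata6 (0.01 and 0.10) stood against Hmga2 (−4.27 and −1.87) and Bmp4 (−0.86 and −0.79). No neuroendocrine gene of 11 reached the CPM minimum. Mesenchymal genes stood at −0.41 and −1.28 over 5 members (percentiles 3.26 and 0.02), with the fibronectin gene Fn1 at −1.34 and −2.32, Mmp14 at −0.41 and −0.92 and Sparc at 0.60 and 0.01. The same-genotype median of the mesenchymal genes in KP was 0.74, larger in size than their pre-depletion genotype median. Fn1 and Mmp14 were higher in non-epithelial cells.

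Lung transcription factors had medians of 0.16 and 0.26 (percentiles 62.6 and 92.7), with Irx2 (1.65 and 2.32), Tead1 (0.97 and 1.21) and Irx1 (0.71 and 1.12) higher, and Id1 (−1.87 and −1.99) and Id2 (−0.45 and −1.08), inhibitors of helix-loop-helix factors, lower. Trp53 stood at 0.08 and −0.08. S phase genes had medians of 0.22 and 0.24 over 4 members (percentiles 74.2 and 79.2), with Pcna at 0.56 and 0.38, Slbp at 0.31 and 0.25, Tyms at 0.13 and 0.23 and Dut at −0.62 and −0.80. Of 21 G2M genes only Ube2c was measured (0.40 and 0.73). The proliferation genes Mki67 (1.24 and 0.95) and Top2a (1.09 and 1.36) were higher in KPF1F2, and also higher in non-epithelial than in epithelial-like cells.

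Antigen presentation and interferon genes were higher in KPF1F2 in every measured member. MHC class II genes had medians of 1.37 and 1.62 over 7 members (percentiles 99.9 and 100), with H2-Eb1 at 1.78 and 2.04, H2-DMb2 at 2.07 and 1.69, H2-Aa at 1.43 and 1.64 and H2-Ab1 at 1.37 and 1.62. MHC class I genes stood at 1.15 and 1.30 over 11 members (percentile 100 in both), with H2-Q7 at 1.58 and 2.14, H2-K1 at 1.35 and 1.47, B2m at 1.28 and 1.65 and Tap2 at 1.15 and 1.20. Interferon response genes stood at 1.76 and 1.42 over 8 members (percentile 100 in both), with Bst2 at 1.99 and 1.59, Ifitm3 at 1.76 and 1.54, Ifit1 at 3.42 and 1.46 and Isg15 at 1.75 and 1.38. NF-kB and chemokine genes stood at 1.03 and 0.89 (percentile 100 in both), with Cxcl2 at 2.26 and 2.45, Nfkbia at 1.54 and 1.09, Cxcl16 at 1.41 and 0.93 and Relb at 1.03 and 0.89. In that list Csf2 changed side, at 0.57 and −1.09. Many of these genes, B2m and Cxcl2 among them, were higher still in non-epithelial cells. The leukocyte gene Ptprc stood at 6.13 and 4.82 CPM in KP and KPF1F2 epithelial-like cells pre-depletion and at 0.372 and 0.454 post-depletion. With 5% free RNA subtracted, the fold of Ifitm3 post-depletion became −2.02. The profile subtracted was that of the non-epithelial cells, whose make-up differed between KP and KPF1F2.

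Lipid synthesis genes were higher over all epithelial-like cells. Fatty acid synthesis genes had medians of 0.55 and 0.55 (percentiles 99.8 and 99.9), with the desaturase Scd1 at 1.33 and 1.79, Elovl5 at 1.19 and 0.95, Acly at 1.00 and 0.81 and Chpt1 at 0.72 and 0.72, against Acsl4 (−0.42 and −0.06) and Me1 (−0.02 and −0.09). All 13 measured cholesterol synthesis genes were higher in both states, with medians of 0.74 and 0.35 (percentiles 100 and 97.5), among them Idi1 (0.90 and 0.96), Acat2 (0.97 and 0.79), Hmgcs1 (0.88 and 0.71) and Insig1 (1.04 and 1.03). Their same-genotype median in KPF1F2 was −0.48, larger in size than the post-depletion genotype median. In cells with a CRE-ERT2 UMI the fatty acid medians were 0.26 and 0.52 (percentiles 61.02 and 99.2), the cholesterol medians were 0.19 and 0.09 (percentiles 52.5 and 38.3), and Insig1 stood at −0.10 pre-depletion. Hypoxia and glycolysis genes stood at −0.05 and −0.18 (percentiles 20.03 and 4.01), with Tpi1 (−0.93 and −1.13), Ndrg1 (−0.53 and −0.50), Gapdh (−0.38 and −0.60) and Bnip3 (−0.40 and −0.29) lower, and Ero1l (0.45 and 0.46) and Aldoa (0.28 and 0.16) higher.

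MAPK output genes stood at 0.25 and −0.02 (percentiles 86.2 and 21.6), with the cyclin Ccnd1 (1.39 and 1.32), Fosl1 (1.21 and 0.97), Myc (0.48 and 0.51) and Phlda1 (0.61 and 0.45) higher, and the phosphatases Dusp6 (−0.90 and −0.81) and Dusp4 (−1.24 and −0.79) lower. YAP target genes stood at 0.52 and 0.49 (percentiles 98.1 and 98.2), with Amotl2 (2.22 and 2.08), Cyr61 (0.53 and 0.83), Arhgef17 (0.52 and 0.56) and Lats2 (0.68 and 0.42) higher, and Nt5e (−0.99 and −1.70) and Ctgf (−1.93 and −0.75) lower. Only 2 WNT targets were measured, Nkd1 (0.72 and 1.07) and Sp5 (−0.06 and −0.09). The p53 targets stood at 0.12 and 0.24 over 5 members (percentiles 55.7 and 79.0), with Ccng1 at 1.28 and 1.04, Ei24 at 0.83 and 0.47, Mdm2 at 0.12 and 0.24 and Bax at −0.13 and −0.16.

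Unfolded protein response genes stood at 0.20 and 0.34 (percentiles 72.2 and 95.8), with Sdf2l1 (1.26 and 1.06), Xbp1 (0.86 and 0.84), Dnajb9 (0.53 and 0.37) and Manf (0.63 and 0.33) higher, and Herpud1 (−0.55 and −0.84) and Atf4 (−0.11 and −0.22) lower. Cell junction genes stood at 0.34 and 0.53 (percentiles 94.9 and 99.9), with 15 of 16 members higher in both states, among them E-cadherin Cdh1 (1.14 and 0.97), Jup (1.05 and 0.74) and Cldn7 (0.85 and 0.74), while Dsg2 stood at −0.16 and −0.07. Dissociation stress genes stood at 0.33 and −0.05 (percentiles 93.8 and 21.6). The heat shock genes Hspa1a (2.16 and 2.25) and Hspa1b (1.97 and 2.27), Nr4a1 (0.60 and 0.68) and Atf3 (0.57 and 0.41) were higher, and Btg2 (−0.92 and −1.16) and Ier2 (−0.55 and −0.80) lower. Hspa1a was also higher over all cells kept, at 326 against 77.9 CPM pre-depletion and 939 against 209 post-depletion.

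**Figure D3:**
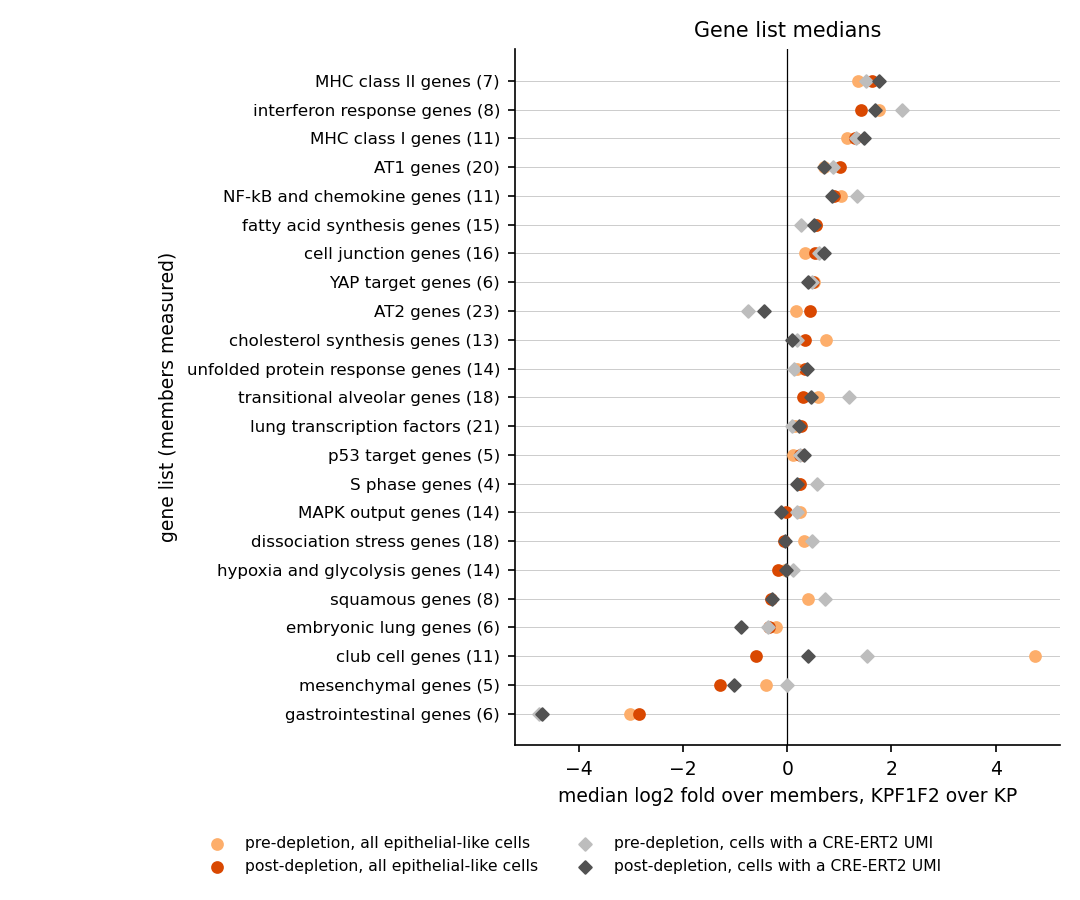
Points give the median log2 fold of KPF1F2 over KP for each gene list with 3 or more measured members (number in brackets), circles for all epithelial-like cells and diamonds for those with a CRE-ERT2 UMI, in both depletion states. Gastrointestinal genes lie lowest (−2.85 post-depletion) and MHC class II genes highest post-depletion (1.62), and type 2 alveolar genes change side in cells with a CRE-ERT2 UMI.

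Before depletion, the KPF1F2 library gave fewer epithelial-like cells and more neutrophil-like and B cell-like cells than the KP library. That pair differs in the leading number of the titles. Epithelial-like cells made up 15.8% (14.7 to 17.1) of KP and 5.21% (4.49 to 6.02) of KPF1F2 cells, a ratio of 0.329 (0.276 to 0.390). Neutrophil-like cells made up 5.20% (4.50 to 5.97) and 15.5% (14.3 to 16.8), a ratio of 2.99 (2.53 to 3.55), and B cell-like cells 4.67% (4.01 to 5.41) and 10.7% (9.64 to 11.8), a ratio of 2.28 (1.89 to 2.75). Macrophage-like (ratio 1.45), monocyte-like (1.97) and dendritic cell-like (1.58) shares were also higher, and alveolar macrophage-like (0.748), T cell-like (0.855) and endothelial-like (0.691) shares lower. With 500 UMIs and no mitochondrial limit the T cell-like ratio was 1.01. Of the alveolar macrophage-like clusters, cluster 0 held 700 KP and 610 KPF1F2 cells, and the shallow cluster 13 (median of 2480 UMIs) 248 and 52. Among cells of the named immune classes alone, neutrophil-like cells were 7.65% (6.63 to 8.77) in KP and 19.2% (17.7 to 20.7) in KPF1F2. Fibroblast-like cells numbered 3 and 35, plasma cell-like cells 1 and 20 and mesothelial-like cells 0 and 11, while ciliated-like cells numbered 7 and 6. The shallow unnamed clusters 4, 8 and 31, with epithelial genes, added 5.81% of cells in KP and 0.267% in KPF1F2.

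**Figure D4:**
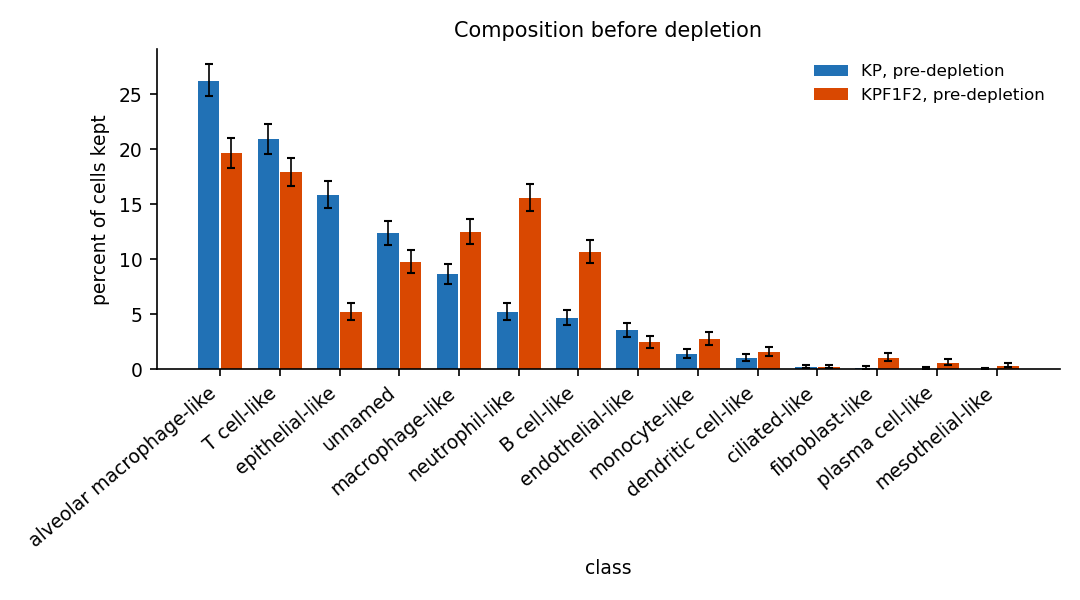
Bars give the percent of cells kept in each class in the 2 pre-depletion libraries, with exact Clopper-Pearson 95% intervals. The epithelial-like share is 15.8% in KP and 5.21% in KPF1F2, and the neutrophil-like share 5.20% and 15.5%.

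Depletion of CD45-positive and CD31-positive cells sets the post-depletion shares. Epithelial-like cells then made up 74.5% of KP and 67.2% of KPF1F2 cells, 4.70-fold (4.29 to 5.16) and 12.9-fold (11.04 to 15.2) their pre-depletion shares. No endothelial-like cell was left, which allows up to 0.0889% in KP and 0.121% in KPF1F2. Fibroblast-like cells, which depletion does not target, made up 0.385% of KP and 9.86% of KPF1F2 cells, a ratio of 25.6 (14.7 to 48.8). That ratio depends on the naming: cluster 24, closest to fibroblasts but left unnamed for its mural cell genes, held 90 KP and 179 KPF1F2 cells post-depletion. Mesothelial-like cells made up 0.415% and 3.35%, a ratio of 8.08 (4.56 to 15.4). Ciliated-like cells numbered 23 in KP and 3 in KPF1F2.

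In the immune classes, which qualified pre-depletion only, where the pair differs in the leading number of the titles, the genes with the largest folds included Igf1 in both macrophage classes and Il13 in T cell-like cells. Macrophage-like cells of KPF1F2 had more Ccl8 (4.33), Cxcl13 (3.82), the growth factor Igf1 (4.12), Rbp4 (4.91) and Lyz1 (3.70). They had less Tnfrsf9 (−4.50), Lepr (−3.54), Mgp (−3.39), Bnip3 (−2.81) and the chemokine Cxcl3 (−2.68); Mgp turned to 0.14 with doublets kept. Alveolar macrophage-like cells also had more Igf1 (4.38), with the collagenase Mmp8 (2.59), complement C4b (2.51), Rasgef1b (1.99) and the lipid transfer gene Pltp (1.83), and less Gdpd3 (−2.54), Lars2 (−2.39), Rgs1 (−1.67), Fstl1 (−1.48) and Lrpap1 (−1.36). Mmp8 helped to define a cluster with 165 KP and 354 KPF1F2 cells at resolution 2, where another of this class held 527 and 253. T cell-like cells of KPF1F2 had more of the cytokine Il13 (133 against 1.53 CPM, 5.73), the granzyme Gzmk (2.81), Nr4a2 (1.93), Hspa1a (5.83) and Hspa1b (5.67). At resolution 2, Il13 helped to define a cluster with 13 KP and 38 KPF1F2 cells. Cluster 10 of the main clustering, which Gzmk helps to define, held 170 of 756 KP and 239 of 604 KPF1F2 T cell-like cells. It includes natural killer cell-like cells, 35 in KP and 7 in KPF1F2, which form their own cluster at resolution 2.

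Neutrophil-like cells of KPF1F2 had more of the interferon-induced Isg15 (3.55) and Ifi27l2a (2.90), Scnn1a (2.96), the lactate transporter Slc16a3 (2.43) and Mrgpra2b (2.39), and less Csrp2 (−3.90) and Cysltr1 (−3.63). Cluster 17 held 155 of 188 KP cells and cluster 15 held 329 of 525 KPF1F2 cells. B cell-like cells had more Hspa1b (5.32), Mndal (1.93), Serpina3g (1.91), Got1 (1.44) and Marcksl1 (1.34), and less Sesn1 (−1.97). Linker histone Hist1h1e, Gdpd3 and AY036118 were among the 5 lowest genes in T cell-like (−2.53, −6.19 and −4.19), B cell-like (−3.02, −5.77 and −4.64) and neutrophil-like cells (−4.38, −4.14 and −3.85). Hist1h1c was lower in T cell-like (−2.01) and B cell-like cells (−2.33), and Igfbp4 in T cell-like cells (−1.93). At least 2-fold higher and lower were 71 and 86 genes in macrophage-like, 61 and 21 in alveolar macrophage-like, 35 and 45 in T cell-like, 116 and 417 in neutrophil-like and 36 and 67 in B cell-like cells. With TMM factors the splits were 98 and 59, 63 and 19, 42 and 34, 533 and 40, and 60 and 50. Those factors shift every fold by 0.77 in neutrophil-like, 0.12 in both B cell-like and macrophage-like and 0.07 in T cell-like cells, so the direction of the split depends on the scaling in all of these.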

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

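All tests in this part were chosen after the results they bear on were seen. UPRT_short is a feature outside the main measurement: it had 1065 UMIs in KPF1F2 pre-depletion and 10230 in KPF1F2 post-depletion over all barcodes, and 0 in both KP libraries. Several club cell and mucus genes stood on opposite sides in the 2 depletion states, while 3 of 11 measured club cell genes were higher in both, and these differences were not tested. The log2 folds pre-depletion and post-depletion were 9.95 and −1.0004 for Scgb1a1, 9.94 and −1.35 for Scgb3a1, 7.70 and −1.47 for Clca1, 6.97 and −2.48 for Reg3g, 3.85 and −1.02 for Bpifa1 and 1.74 and −4.51 for Muc5b. All of these genes were among the leading genes of cluster 34. It held 0 KP and 6 KPF1F2 cells pre-depletion and 27 and 7 post-depletion. The folds went in the direction of these cell numbers, and a fold over the whole class does not separate them from RNA per cell. The median of the club cell genes was 4.76 and −0.60. In cells with a CRE-ERT2 UMI it was 1.53 and 0.41, on the same side in both states, and several other settings turned the post-depletion median positive.

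Foxa1_2 was lower in KPF1F2 epithelial-like cells, more so post-depletion. A difference between libraries in how Foxa1 reads were counted is argued against: in cluster 1, Foxa1_2 in KPF1F2 over KP post-depletion was 1.17 (0.875 to 1.56). The cells compared are not alike, since CRE-ERT2 in that cluster stood at 0.984 CPM in KPF1F2 and 13.8 in KP. Recombination in cells that carry the Cre transgene may account for the lower Foxa1_2, since Foxa1_2 in clusters 3 and 21, rich in CRE-ERT2, was 0.0412 (0.0240 to 0.0672) of that in cluster 1 of the same library, at 0.555 against 13.5 CPM. What the pieces cover stays open, and so does Foxa2, whose pieces had too few UMIs.

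Gastrointestinal genes were lower in KPF1F2. A smaller share of tumour cells among KPF1F2 epithelial-like cells is argued against, since among cells with a CRE-ERT2 UMI post-depletion Gkn2 stood at −9.61, Tff1 at −6.35 and Ctse at −4.70. The list median there was also −4.70, over 5 measured members and not 6, so its distance from −2.85 reflects the membership. A difference tied to the leading title number is argued against for Gkn2, Tff1 and Ctse by the post-depletion pair, which shares it. They stood there at −9.18, −5.45 and −4.83, while Cldn2 and Psca were lower by less and Pigr was higher. The median of that pair was −2.85, but −0.44 with equal weight per cell. The labels do not say what the number stands for, so other differences in preparation or sequencing stay open. Sex of the mice cannot be told apart from genotype, because Xist was at 0.324 CPM in KPF1F2 post-depletion and high in both KP libraries. Loss of Foxa1 and Foxa2, the difference the design names, stays open as a hypothesis beside sex and other differences between single mice. UPRT_short, found only in the KPF1F2 libraries, is a further difference that goes with genotype, and the labels do not say what it is.

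AY036118, a long non-coding gene on chromosome 17 (39847113 to 39848035) that overlaps Gm42418 on the other strand, stood at 691 CPM in KP and 70.8 in KPF1F2 over all cells kept pre-depletion, and at 702 and 1453 post-depletion. Genotype is argued against, since KPF1F2 over KP was 2.07 (2.04 to 2.10) post-depletion. A difference of the KPF1F2 pre-depletion library alone may account for it: KPF1F2 pre-depletion over KPF1F2 post-depletion was 0.0487 (0.0470 to 0.0505). That library is also the only one whose title begins with 18385. Depletion state alone does not bring such a difference in KP, whose libraries share a title number. An effect of depletion in KPF1F2 only was not separated from other differences of the KPF1F2 pre-depletion library.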

How the results depend on the processing

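Settings added after the data were seen were cells with a CRE-ERT2 UMI, no clusters low in CRE-ERT2, the shallow clusters and genes outside chromosomes X and Y. Of 7046 pairs of a log2 fold and an alternative, 6945 (98.6%) kept their sign, as did all 864 pairs of the 24 genes that led the ranking. These shares overstate stability. The CPM minimum, the added CPM and the choice of chromosomes cannot change the sign of a single gene's fold. The 24 genes were also picked for large folds in these same data. Of 190 pairs of a main result and an alternative, 153 stayed the same. For shares and their ratios this meant within the counting interval, and for counts of genes within 1.5 times. List medians had to move by less than the larger same-genotype difference of the list. No paired analysis was made. Each group holds a single library, the labels do not say which libraries share mice, and the result comes from no test. Causes below were not tested unless stated. The CPM minimum sets the counts by construction: without it, 439 genes were higher and 529 lower, with 313 and 517 between the KP and the KPF1F2 libraries, and with a minimum of 100 CPM 64, 29, 15 and 21. Without clusters low in CRE-ERT2, 312 genes were higher. The type 2 median turned to −0.44 in cells with a CRE-ERT2 UMI and was 0.15 without clusters low in CRE-ERT2 and 0.27 with equal weight per cell. The type 1 median was 0.72 with 100 CPM and 0.71 in cells with a CRE-ERT2 UMI. The gastrointestinal median, in a gap between members, stayed negative: −2.90 with TMM, −2.91 with DESeq2, −1.99 with no minimum, −2.95 and −1.98 with 0.1 and 5 CPM added, −0.44 with equal weight per cell, −2.69 by the marker rule, −2.78 without Mki67 and Top2a UMIs, −4.70 in cells with a CRE-ERT2 UMI, and −4.83 both without low clusters and outside X and Y, where Cldn2 drops out. The club cell median turned to 0.33 with doublets kept, 0.84 at resolution 0.5, 0.16 without Mki67 and Top2a UMIs, 0.41 in cells with a CRE-ERT2 UMI and 1.45 without low clusters, and the squamous median to 0.0188 with no minimum. Insig1 turned to −0.10 in cells with a CRE-ERT2 UMI, Ifitm3 to −2.02 with free RNA subtracted and Mgp in macrophage-like cells to 0.14 with doublets kept. Shares with a UMI follow depth by construction: thinned to 1500 UMIs, Hnf4a was found in 3.03% of KP and 0% of KPF1F2 cells and Nkx2-1 in 21.5% and 25.4%, and unthinned in 22.7%, 0.481%, 71.9% and 83.2%; Nkx2-1 in KPF1F2 was 39.4% by the marker rule. With 500 UMIs and no mitochondrial limit, the KPF1F2 over KP ratio was 0.268 for epithelial-like, 2.84 for B cell-like and 1.01 for T cell-like cells, the last a change of side. TMM factors turned the split of higher and lower genes to 60 and 50 in B cell-like, 42 and 34 in T cell-like, 98 and 59 in macrophage-like and 533 and 40 in neutrophil-like cells. Depth limits most what can be said of KPF1F2 pre-depletion, with 176 epithelial-like cells.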

Other observations

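The values for cells with a CRE-ERT2 UMI and by cluster were chosen after the data were seen. KP tumours held a group of epithelial-like cells with little Nkx2-1. Cluster 28, with 99 cells in KP post-depletion and 0 in KPF1F2, had Nkx2-1 at 5.78 CPM (3.58 to 8.83) and the embryonic chromatin gene Hmga2 at 435 (414 to 457), with Ager at 16.5 and Hnf4a at 8.26. In cluster 9, the KP cells had Nkx2-1 at 152, Hnf4a at 51.6 and Foxa3 at 38.0 CPM post-depletion. In KPF1F2 post-depletion, cluster 3 had Nkx2-1 at 273, Ager at 3790 and Sftpc at 8461 CPM, with 0 Hnf4a UMIs, and cluster 21 had Nkx2-1 at 90.05, Ager at 243, Sftpc at 519 and Hmga2 at 53.1 CPM. A cluster mostly of 1 library can stand for that library and not for a cell state.

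Of the 16 Hnf4a UMIs in KPF1F2 epithelial-like cells post-depletion, 12 (75.0%) came from 49 cells of cluster 20, where Hnf4a stood at 21.6 CPM (11.1 to 37.7), against 43.6 (39.96 to 47.4) in the KP cells of that cluster. Those 49 cells had 1 UMI of Foxa1_2, Nkx2-1 at 25.2 CPM, and UPRT_short in 21 cells (42.9%, 28.8 to 57.8). Foxa3 was at 16.2 CPM (7.39 to 30.7) in them and at 2.35 (1.69 to 3.19) in cluster 3 of the same library.

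The heat shock gene Hspa1a differed by class pre-depletion. Its ratio in KPF1F2 over KP was 67.4 (43.9 to 109) in T cell-like, 54.8 (18.6 to 267) in B cell-like, 13.3 (11.2 to 15.9) in alveolar macrophage-like, 7.47 (6.58 to 8.51) in macrophage-like and 4.49 (4.26 to 4.72) in epithelial-like cells, and 0.506 (0.311 to 0.829) in neutrophil-like cells, where that of Hspa1b was 0.911 (0.619 to 1.36). Lars2, a mitochondrial tRNA synthetase gene, stood at 764 CPM in KP and 119 in KPF1F2 over all cells kept pre-depletion and at 640 and 847 post-depletion, and Gm42418 at 25710 and 4516, and 24472 and 36036.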
